A study of Homo sapiens with 2 samples.

How the data were processed

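Gene expression was measured by RNA sequencing in 2 libraries of PC3 cells, 1 with a control shRNA and 1 with an shRNA against KLF16. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA, HISAT2 and the genome build hg19. Their versions, the quantification tool and the annotation release are not given in the sources used here. The values deposited by the authors are TPM per gene, to 2 decimals, a relative abundance scaled to the same total in each library. TPM keeps no depth, so no counting interval or detection floor was computed, and a value of 0 is described only as listed at 0. The columns were matched to the samples by their abbreviated names (KD and Scr), and 0 columns of per-sample values were left unmapped.

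The table held 58591 lines, of which 2 named no gene and were left out. The other 58589 comprised 58233 Ensembl identifiers and 356 loci assembled by the authors. Symbols were taken from a table of gene names, which matched 57392 identifiers, and otherwise from GENCODE 29, which also gave gene types and transcript sequences. GENCODE 29 uses another build than the submitters' notes name, so no coordinates are given.

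Differences were computed as log2((TPM in KLF16 shRNA + 1)/(TPM in control + 1)), for the 14941 rows with a mean of at least 1 TPM over both libraries. With 1 library per group there was no test, standard error or p-value. Genes were described by a size threshold of 1 log2 unit, a 2-fold ratio on this scale. KLF16 was also ranked among the 500 genes nearest in mean TPM. For each list, the median difference of its measured members was placed among the medians of 10000 random lists drawn from the same of 20 equal-sized bins of mean TPM. Lists with at least 5 measured members were called apart outside the central 95% of the random medians, and 5% of the lists tested are expected there by chance.

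The size threshold, the list members, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. The rule took KLF16, the 12 highest and 12 lowest differences among genes with a mean of at least 5 TPM and values above 0 in both libraries, up to 5 genes per direction listed at 0 in the other library, the 2 highest and 2 lowest members of each list, and up to 6 members in the direction of the median for lists called apart. MT-ATP8 was chosen after its values were seen. Some genes that the rule takes, and the result of 1 list, which is counted among the 10 lists called higher, are not reported here. The 37 lists covered the KLF and SP family, cell cycle, MYC, apoptosis, lipid and energy metabolism, mitochondria, ribosomes, histones, interferon, NF-kB, stress responses, immediate early genes, epithelial, mesenchymal, adhesion, YAP and TGF-beta, Wnt and Notch, androgen receptor, neuroendocrine, dopamine receptor, DNA repair, tRNA synthetase, lysosome, receptor kinase and noncoding RNA genes, and markers of 4 other cell types.

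Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, a 1.5-fold threshold, rescaling by the median or a trimmed mean of ratios, leaving out abundant genes, and 5, 50 or no bins for the random lists. Protein-coding genes alone and removal of a trend on transcript length and GC content were added after the data were seen. A result was taken as kept when it stayed on the same side of the size threshold, or of the percentile limits for lists, and a count when it stayed within 1.5 times. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Simulated data for this comparison covered 14941 genes, with noise of 0.3 log2 units (SD). Changed genes were drawn only from those with a mean of at least 5 TPM, so their recovery does not cover lower levels. Of these, 93 of 100 changed by 1.5 log2 units and 100 of 100 changed by 3 passed the size threshold. Of 14741 unchanged genes 3 passed it. The simulation used the same noise SD for all genes, whereas the observed differences spread more widely at low TPM. From 1 to 5 TPM their 2.5 and 97.5 percentiles were -1.29 and 1.64. The simulated counts therefore cannot tell how many genes past the threshold in the data reflect noise, above all at low TPM. With independent noise 2 of 31 unchanged lists were called apart, and 30 of 31 lists shifted by 0.3 log2 units were called higher. The lists were simulated with the same noise SD. From 5 to 20 TPM the observed 2.5 and 97.5 percentiles, -0.92 and 1.00, were also wider than that noise. The list counts therefore do not show the recovery at the spread of the data.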

Results

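RNA from PC3 cells, an established human prostate cancer cell line, was sequenced after expression of an shRNA against KLF16 or of a control shRNA. KLF16 is a zinc-finger transcription factor of the KLF and SP family, which binds GC-rich promoter elements. Each shRNA was represented by 1 library, so no difference given here has a replicate check and no test between the conditions was possible. The values were in TPM, a length-normalised relative abundance that keeps no record of sequencing depth, so the depth of each library is unknown. The control library listed 14836 genes and assembled loci at 1 TPM or more, and the KLF16 shRNA library listed 14945. Mitochondrially encoded mRNA made up 15.2% of the control library and 16.8% of the KLF16 shRNA library, and cytosolic ribosomal protein mRNA made up 10.1% and 9.84%. MT-ATP8 was the row with the highest TPM in both, at 34402 and 40011 TPM.

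The comparison asked how the transcriptome of PC3 cells differed with KLF16 interference. KLF16 (ENSG00000129911, on chromosome 19) was listed at 32.5 TPM in the control library and 11.3 TPM in the KLF16 shRNA library, which was 34.9% of the control level. Its log2 difference was -1.44, and 3 of the 500 genes nearest to it in mean TPM had a difference as low. The lists of G2/M and mitosis, of the MYC family and nucleolar MYC targets, and of mitochondrial genome expression and biogenesis were lower in the KLF16 shRNA library, by modest amounts that most members shared. The lists of cell adhesion and matrix remodelling, of receptor tyrosine kinases and their ligands, and of immediate early genes were higher, with some members differing several-fold. All differences are log2 ratios of TPM + 1, KLF16 shRNA over control, a scale that understates the difference of genes with low values.

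Of the 14941 genes and loci with a mean of at least 1 TPM, 470 were higher by 1 log2 unit or more and 318 were lower, and the median difference of all of them was -0.04. These counts depend on the pseudocount, with 156 higher and 96 lower when it was 5 in place of 1. Protein-coding genes accounted for 232 of the higher and 157 of the lower genes, out of 12211 measured. Processed pseudogenes exceeded the threshold more often, with 39 higher and 21 lower of 231, as did assembled loci without an Ensembl identifier, with 71 higher and 24 lower of 330. The spread narrowed with expression. From 1 to 5 TPM the central 95% of differences ran from -1.29 to 1.64, and at 100 TPM or more it ran from -0.69 to 0.62.

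Among genes with a mean of at least 5 TPM and values above 0 in both libraries, CTNNA2, which encodes an alpha-catenin of neuronal cell junctions, was listed at 0.04 TPM in the control and 26.5 TPM in the KLF16 shRNA library. CCDC62 was at 0.27 and 13.7 TPM, TMEM91 at 1.59 and 25.6 TPM, and VXN at 1.08 and 13.1 TPM. KRT6C, an epithelial keratin, was at 1.18 and 22.4 TPM, and its sequence is close to that of KRT6A and KRT6B, so its level is uncertain. HAS2, a hyaluronan synthase, was at 2.46 and 26.2 TPM (log2 difference 2.97), and GDF15, a secreted stress-induced cytokine, at 7.40 and 57.1 TPM (log2 difference 2.79). TRBC2, a T cell receptor constant segment, was at 1.93 and 21.1 TPM, and RN7SL731P, a pseudogene of the signal recognition particle RNA, at 0.01 and 12.3 TPM. Pseudogenes resemble their parent genes in sequence, so the levels of RN7SL731P and of the pseudogenes named below are also uncertain. The remaining 3 of the 12 highest were assembled loci, of which MSTRG.20473 had the largest difference, with 6.28 and 201 TPM.

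Among genes with a mean of at least 5 TPM and values above 0 in both libraries, the lowest differences belonged to SERPINB4 and SERPINB3, adjacent serpins of squamous epithelia with nearly identical sequences. SERPINB4 was at 32.2 TPM in the control and 0.69 TPM in the KLF16 shRNA library, and SERPINB3 at 63.5 and 3.42 TPM, with the division between the pair uncertain. KLK5, a kallikrein protease of epithelia, was at 170 and 30.9 TPM (log2 difference -2.42). KRT34, a hair keratin, was at 21.7 and 1.31 TPM, PDZK1IP1 at 56.4 and 7.59 TPM, and TIAM2, an exchange factor for RAC GTPases, at 38.6 and 6.38 TPM. LEKR1 was at 16.3 and 2.36 TPM. The others were the pseudogene PDE4DIPP2 at 47.4 and 3.54 TPM, LINC01764 at 20.2 and 2.76 TPM, HIF1A-AS3 at 125 and 22.7 TPM, the antisense gene ENSG00000257500 and an assembled locus. Whether counting used strand is not given in the sources used here, so antisense genes cannot be separated from the genes they overlap.

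In the control library, 95 measured rows were listed at 0, and 64 were listed at 0 in the KLF16 shRNA library. Those with the highest TPM in the other library were mainly pseudogenes, short RNAs and assembled loci. RPL39P38 was listed at 0 in the control and 43.0 TPM in the KLF16 shRNA library, and SEPTIN14P2 at 0 and 38.7 TPM. The row ENSG00000212440 on chromosome 12, named SNORA75 for a small nucleolar RNA, was listed at 40.4 TPM in the control and 0 in the KLF16 shRNA library. RF02164 was listed at 65.3 TPM and 0, and CCDC144NL at 37.7 TPM and 0.

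Of 37 gene lists fixed in advance, 31 had at least 5 measured members. The median differences of 10 lists lay above and those of 7 below the central 95% of 10000 random lists matched on mean expression, against 1.55 lists expected by chance. These percentiles describe this pair of libraries. Random lists draw genes independently while members of a pathway vary together, so a list can stand apart through any difference between the cultures.

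**Figure D1:**
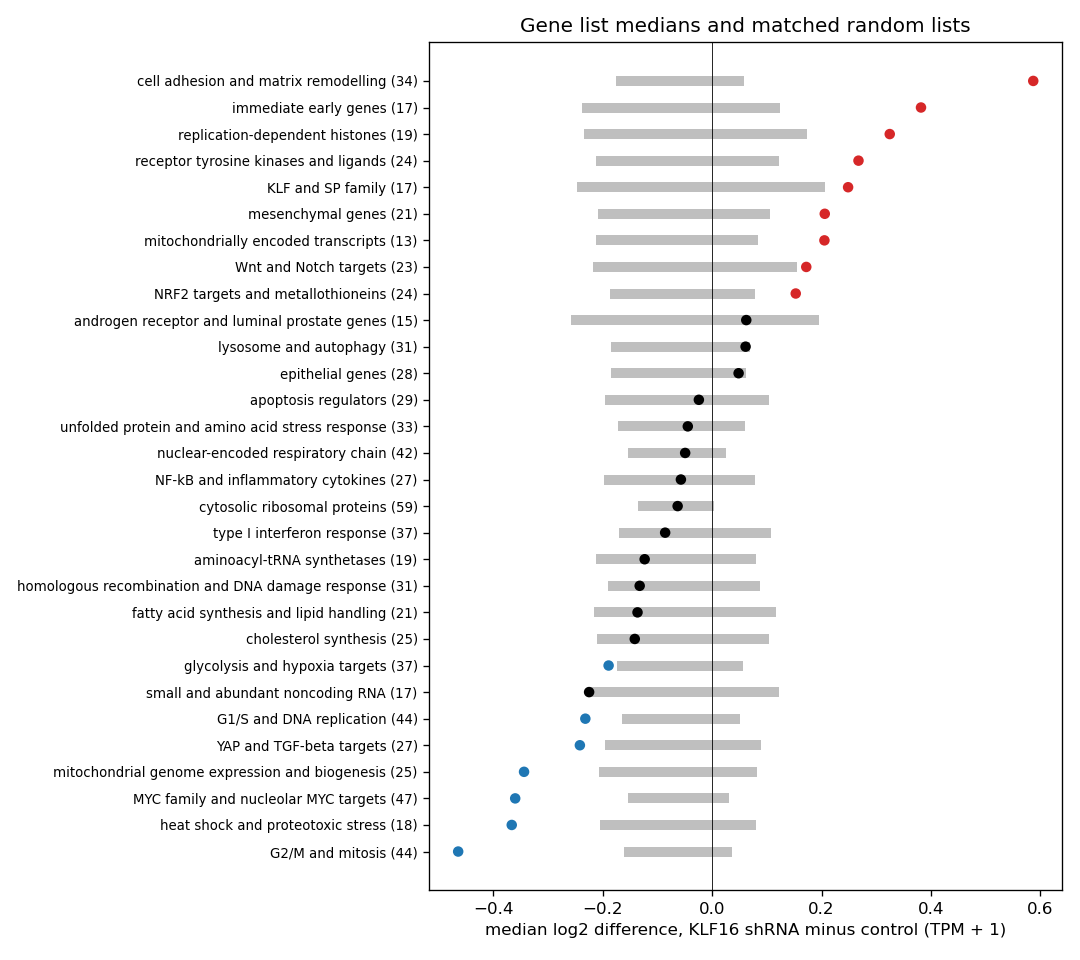
Points are the median log2 differences (KLF16 shRNA minus control, TPM + 1) of 30 of the 31 lists, with the number of measured members in parentheses, and grey bars span the central 95% of 10000 matched random lists. Red points lie above and blue points below those ranges, from -0.46 for mitosis genes to 0.59 for adhesion genes.

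Cell adhesion and matrix remodelling genes had the highest median, 0.59, above all 10000 random lists. Of 34 measured members 11 were higher by at least 1 log2 unit, 0 were lower by that much, and 23 lay between. PLAT and PLAU, the plasminogen activators, were at 6.24 and 497 TPM in the control and 35.2 and 1716 TPM in the KLF16 shRNA library (log2 differences 2.32 and 1.79). ITGA2, an integrin subunit of the collagen receptor, was at 15.3 and 60.3 TPM, ITGB6 at 2.88 and 10.02 TPM, and the matrix protease gene MMP14 at 35.0 and 114 TPM. SERPINB2, an inhibitor of plasminogen activators, was lower at 28.7 and 15.0 TPM, and the caveolin gene CAV1 at 480 and 272 TPM.

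Receptor tyrosine kinases and their ligands had a median of 0.27 (percentile 99.96), with 3 of 24 members higher by the threshold and 0 lower. IGF2 was at 4.39 and 30.6 TPM, the EGFR ligand gene AREG at 17.3 and 86.8 TPM, and the ephrin receptor gene EPHB2 at 11.6 and 33.8 TPM, while IGF1R was at 6.33 and 3.22 TPM and FGF2 at 26.4 and 14.1 TPM. Immediate early genes had a median of 0.38, above all random lists, with 3 of 17 higher and 0 lower. DUSP6, a phosphatase of ERK, was at 11.6 and 39.2 TPM, IER3 at 369 and 789 TPM and RHOB at 11.8 and 24.7 TPM, while NR4A1 was at 11.3 and 5.20 TPM. Mesenchymal genes had a median of 0.21 (percentile 99.77), with SNAI2 at 13.3 and 31.1 TPM and VIM at 41.3 and 85.1 TPM above the threshold and TAGLN at 33.4 and 13.9 TPM below it. Epithelial genes had a median of 0.05 (percentile 95.87), inside the random range, with MUC1 at 5.06 and 9.79 TPM and KRT17 at 4.26 and 1.36 TPM. Wnt and Notch targets had a median of 0.17 (percentile 98.40). JAG1, a Notch ligand, at 5.54 and 24.6 TPM was the 1 member of 23 past the threshold. Despite its name, the list also holds ligands and receptors of these pathways, so it does not measure targets alone. This list lay inside its random range with 50 bins of expression in place of 20, at a median of 0.17, and without the length and GC trend, also at 0.17. YAP and TGF-beta targets had a median of -0.24 (percentile 0.48), with 3 of 27 lower and 1 higher. In that list ANKRD1 was at 38.7 and 9.16 TPM, ID3 at 24.0 and 10.6 TPM and CRIM1 at 79.4 and 38.1 TPM, while PMEPA1 was at 65.2 and 138 TPM. With a pseudocount of 5 in place of 1, RHOB, SNAI2, VIM, KRT17, ID3 and CRIM1 moved inside the threshold.

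Genes of G2/M and mitosis had a median of -0.46, below all 10000 random lists, and 42 of 44 members had a difference below 0. CDCA3, at 87.5 and 37.4 TPM, was the 1 member lower by at least 1 log2 unit. CDC20, the activator of the anaphase-promoting complex, was at 211 and 116 TPM, and the cyclin gene CCNA2 at 61.5 and 34.2 TPM, while FOXM1 was at 88.9 and 92.5 TPM. G1/S and DNA replication genes had a median of -0.23 (percentile 0.06), with 34 of 44 below 0 and 0 past the threshold. GINS4 was at 23.7 and 12.2 TPM and the helicase subunit gene MCM2 at 69.6 and 43.5 TPM, whereas the cyclin genes CCNE1 and CCNE2 were at 13.9 and 19.4 TPM in the control and 17.9 and 25.6 TPM in the KLF16 shRNA library.

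The MYC family and nucleolar MYC targets had a median of -0.36, below all random lists, and 46 of 47 members had a difference below 0, with 0 past the threshold. GRWD1 was at 45.8 and 29.5 TPM, PUS1, a pseudouridine synthase, at 55.6 and 35.9 TPM, and RRS1, a ribosome assembly factor, at 93.7 and 62.1 TPM. The exception was MYC, at 192 and 257 TPM (log2 difference 0.42). Genes of mitochondrial genome expression and biogenesis had a median of -0.34 (percentile 0.01), with 24 of 25 members below 0. The translation factor genes MTIF2 and TUFM were at 60.6 and 192 TPM in the control and 32.7 and 137 TPM in the KLF16 shRNA library. The 13 mitochondrially encoded transcripts had a median of 0.21 (percentile 99.97), with MT-CYB at 3330 and 4218 TPM and MT-ND6 at 4419 and 4194 TPM. Against random lists not matched on expression their median of 0.21 was inside the random range. Heat shock genes had a median of -0.37, below all random lists, with 17 of 18 members below 0. HSPA8, a constitutive HSP70 chaperone, was at 2822 and 1833 TPM, DNAJB1 at 146 and 78.9 TPM and HSPA1A at 188 and 110 TPM, and CRYAB, at 2.59 and 0.58 TPM, was the 1 member past the threshold. HSPA1A and HSPA1B are near-identical copies, so their division is uncertain.

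**Figure D2:**
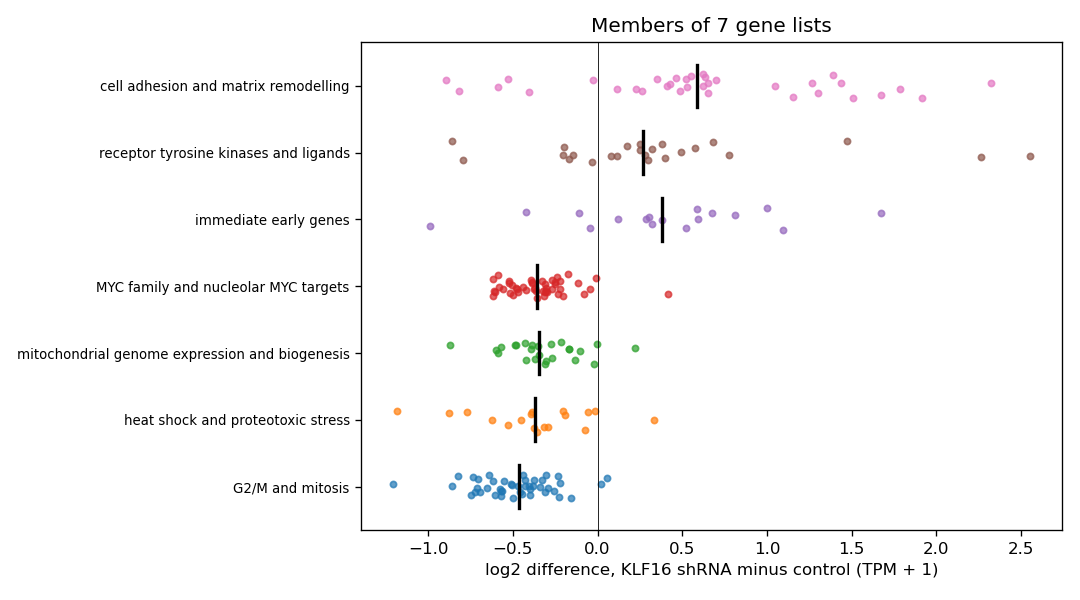
Each point is a measured member of 7 gene lists, placed by its log2 difference (KLF16 shRNA minus control, TPM + 1), and black bars are list medians. Vertical scatter within a list only separates the points, and the medians run from -0.46 for mitosis genes to 0.59 for adhesion genes.

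Glycolysis and hypoxia targets had a median of -0.19 (percentile 1.35), with 3 of 37 lower and 0 higher. These were CA9, a carbonic anhydrase gene, at 9.28 and 1.37 TPM, ADM, the adrenomedullin gene, at 131 and 38.8 TPM, and the glycolytic enzyme gene PGAM1 at 436 and 182 TPM. P4HA2 was higher, at 21.5 and 39.1 TPM. The list was divided, with 26 members below 0 and 11 above 0. NRF2 targets and metallothioneins had a median of 0.15 (percentile 99.82) with members on both sides. AKR1B10 was at 3.68 and 10.5 TPM and the ferritin heavy chain gene FTH1 at 5408 and 9603 TPM, while the metallothionein genes MT1X and MT1F were at 410 and 22.0 TPM in the control and 132 and 7.42 TPM in the KLF16 shRNA library. Replication-dependent histones had a median of 0.32 (percentile 99.91), with 17 of 19 members above 0, and H3C1 was at 0.96 and 4.25 TPM and H2AC20 at 10.4 and 4.46 TPM. The other members of the KLF and SP family had a median of 0.25 (percentile 99.01) and 0 of 17 past the threshold. Their median was inside its random range, at 0.21, after removal of a trend on transcript length and GC content, a setting added after the data were seen. In this family KLF12 was at 1.04 and 3.01 TPM, KLF13 at 9.05 and 17.3 TPM, SP5 at 4.14 and 2.94 TPM and SP4 at 3.48 and 2.46 TPM.

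The other 13 lists with at least 5 measured members lay within their random ranges. NF-kB and inflammatory cytokine genes had a median of -0.06 (percentile 50.5) while members differed in both directions. CSF2, which encodes GM-CSF, was at 9.89 and 46.5 TPM and IL1B at 627 and 1326 TPM, whereas the chemokine gene CCL20 was at 18.0 and 5.07 TPM and CSF1 at 11.9 and 5.09 TPM. Type I interferon response genes had a median of -0.09 (percentile 21.8), with IFI44L at 0.82 and 4.52 TPM and HLA-B at 171 and 71.3 TPM. Androgen receptor and luminal prostate genes had a median of 0.06 (percentile 81.1), with TMPRSS2 at 1.79 and 4.87 TPM and KLK4 at 1.81 and 0.30 TPM. Small and abundant noncoding RNAs had a median of -0.23 (percentile 2.73), with RPPH1 at 1.80 and 5.81 TPM and GAS5 at 146 and 88.7 TPM. Lysosome and autophagy genes had a median of 0.06 (percentile 97.0), with CTSL at 36.0 and 58.4 TPM. Medians were -0.14 (percentile 12.7) for cholesterol synthesis, -0.14 (percentile 15.1) for fatty acid synthesis and lipid handling, -0.13 (percentile 12.4) for homologous recombination and the DNA damage response, and -0.12 (percentile 21.5) for aminoacyl-tRNA synthetases. Cytosolic ribosomal proteins had a median of -0.06 (percentile 49.4), the nuclear-encoded respiratory chain -0.05 (percentile 65.9), the unfolded protein and amino acid stress response -0.04 (percentile 61.2) and apoptosis regulators -0.02 (percentile 62.6).

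The remaining 6 lists had fewer than 5 members at a mean of 1 TPM. In the neuroendocrine list the member with the highest mean TPM was TUBB3, at 91.3 and 114 TPM. Among markers of other cell types, those with the highest mean TPM of both libraries were COL6A3 for fibroblasts at 7.34 and 35.0 TPM, CD68 for immune cells at 55.2 and 26.5 TPM, ESAM for endothelial cells at 1.42 and 3.51 TPM, and NEFL for embryonic kidney cells at 7.90 and 29.4 TPM. No dopamine receptor gene reached a mean of 1 TPM, and DRD2, with the highest mean, was listed at 0 and 0.20 TPM.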

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

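Protein-coding genes alone and the removal of a trend on transcript length and GC content were chosen after the data were seen; the other alternatives were planned. KLF16 was lower by more than the threshold in all 6 alternatives, from -1.51 with a pseudocount of 0.1 to -1.20 with a pseudocount of 5. Counts of higher and lower genes were 737 and 575 with a pseudocount of 0.1, 156 and 96 with 5, 203 and 152 at a mean of at least 5 TPM, 1269 and 1238 with a 1.5-fold threshold, and 232 and 157 for protein-coding genes. Fewer rows enter the filtered counts, and the pseudocount acts on low values by construction. Rescaling moved the log2 differences by 0.06 (median) and 0.05 (trimmed mean), and the counts stayed within 1.5 times.

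Of the 17 lists called apart, 14 stayed apart in the same direction in every alternative that gave a value, and none reversed. Among these alternatives, median rescaling multiplies 1 library by a common factor. It can hardly move a percentile and so tests little. The KLF and SP list had a median of 0.21 without the length and GC trend, inside its random range. Mitochondrially encoded transcripts, at 0.21, were inside the range without matching, and Wnt and Notch targets were inside it with 50 bins (0.17) and without the length and GC trend (0.17). The lysosome list moved outside with 50 bins (0.061). The noncoding RNA list moved outside with a pseudocount of 5 (-0.22), at a mean of at least 5 TPM (-0.29), without abundant genes (-0.22) and without the length and GC trend (-0.23). The cause was not tested. Without abundant genes the mitochondrially encoded and ribosomal protein lists gave no value. Of 1062 values of 215 named genes, 19 moved inside the size threshold, 14 moved outside it and 0 reversed. Those inside included CRYAB, ITGB6, H3C1, H2AC20 and AKR1B10 with a pseudocount of 5. No paired analysis was possible because each group had 1 library, for which reason no library could be left out either. Unknown depth limits what can be said of genes with low TPM.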

Other observations

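All tests in this part were chosen after the data were seen, and what the test of transcript length and GC content would show was written down before its own result; the gene families and genes of the next paragraph were also chosen after their values were seen. Symbol families with at least 8 measured protein-coding genes numbered 189, of which 18 lay below and 15 above the central 95% of matched random lists, against 4.73 expected on each side. Mitochondrial ribosomal proteins were lower, with 46 of 49 MRPL genes (median -0.25) and 25 of 29 MRPS genes (median -0.27) below 0, as were 28 of 31 POLR genes of RNA polymerases (median -0.26). Zinc-finger genes named ZNF had a median of -0.13 over 350 genes. Genes named PRSS, for serine proteases, had a median of 0.54 over 10 genes, with PRSS3 at 21.6 and 81.1 TPM. Those named ADAM had a median of 0.40 over 10 genes, with ADAM19 at 16.9 and 73.1 TPM.

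Single genes chosen after their values were seen were listed as follows. The kallikrein gene KLK6 was at 281 TPM in the control and 126 TPM in the KLF16 shRNA library, S100A8 at 88.6 and 18.2 TPM, SAA1 at 580 and 178 TPM and DEFB4A at 9.95 and 1.44 TPM. SERPINB5 was at 22.3 and 52.8 TPM, KRT6A at 23.8 and 58.3 TPM and LCN2 at 7446 and 11361 TPM. HSD17B10, a mitochondrial dehydrogenase gene, was at 106 and 23.4 TPM. HAS2-AS1, antisense to HAS2, was at 0.88 and 9.34 TPM.

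The MYC target, mitosis and mitochondrial expression lists were lower while the adhesion list was higher. A trend on transcript length and GC content is argued against as the whole cause, since 4 of the 4 lists stayed outside their random ranges after its removal. Fibroblasts as a large part of the culture are argued against by the 10 fibroblast markers, whose median in the KLF16 shRNA library was 0.11 TPM. However, 3 of the markers were at 1 TPM or more in that library and 2 in the control, and COL6A3 was higher. The median of the markers cannot exclude a small share of fibroblasts. Differences in culture density or harvest cannot be told apart from an effect of the shRNA with 1 library per shRNA. An effect of KLF16 itself, or of the shRNA on other transcripts, may also account for the pattern and was not tested.

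Short transcripts exceeded the size threshold often. From 1 to 20 TPM, 85 of 129 genes with a longest transcript under 300 bases did so, against 472 of 8290 longer ones, shares of 65.9% and 5.69% with a ratio of 11.6. Few reads behind the TPM of short transcripts may account for this. A shift of short transcripts in 1 direction stays open, since 62.4% of the 85 were higher (exact binomial 95% interval 51.2% to 72.6%, counting error only), against 58.1% of the longer ones. Small nuclear RNAs had 11 of 14 higher, 0 lower and a median of 1.88.

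Replication-dependent histones were higher while replication genes were lower, and since histone mRNAs mostly lack a poly(A) tail, a larger share of such RNA in the KLF16 shRNA library is a candidate explanation. The median of 6 other RNAs without a tail was 0.33, but 4 were higher and 2 lower, from RPPH1 at 1.28 to RMRP at -0.86, with an SD of 0.83. RMRP has 2 rows, of which the row with the higher mean TPM was taken. With its other row, listed at 0 in both libraries, the median was 0.33 again, with 4 higher and 1 lower. That would meet the limit set for this explanation, but only because a lower member is replaced by a row that holds no difference. The spread and this dependence on 1 row leave the explanation open. Small nuclear RNAs, which also lack a tail, went in its direction. Other classes of noncoding RNA were divided by the size threshold. Small nucleolar RNAs had 3 of 10 higher and 1 lower, and RNAs typed as miscellaneous had 12 of 35 higher and 9 lower. Their medians, 0.45 and 0.28, lay above 0, as did that of small nuclear RNAs.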
